A study of Homo sapiens with 6 samples.

How the data were processed

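Gene expression was measured by RNA sequencing of total RNA in 6 libraries of the cell line C4-2B-ENZR, 3 with a negative-control siRNA and 3 with an siRNA against RUVBL1. Groups and replicate numbers were taken from the labels. The deposited values are estimated counts per gene, not scaled to library size: they are at least 0, between 87.8% and 90.5% of them, zeros included, are exactly whole (no tolerance), and their totals differ between libraries. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse genome builds mm8 and mm9 were named, which conflicts with the human cells of the labels and with the human Ensembl gene identifiers of the deposited count files. The counter, the human genome build, the annotation, the strand setting and any filter are not given in the sources used here, so no coordinates are printed and reads of overlapping or antisense genes may not have been told apart.

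Each file held 57820 genes. Symbols were taken by stable identifier from a table of gene names, which matched 51996 genes and left 5824 without a symbol. Gene type, median transcript length and GC content came from GENCODE 29, and 52337 genes had a length and GC content. The estimated counts were rounded to whole numbers, which changed the library totals by at most 0.000222%.

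Library totals ran from 18985542 to 36054489 counts. No 2 files were identical. Over genes with at least 100 counts in a pair of libraries, and leaving out genes at 0 in both replicate 1 libraries, the mean chi-square per gene was 1.71 for control replicates 2 and 3, 1.75 for RUVBL1 siRNA replicates 2 and 3, and between 3.29 and 3.97 for replicate 1 against another library of its group. All pairs therefore differed by more than counting noise, and each library was counted as 1 replicate. This does not show that the libraries came from separate cultures. In edgeR, the coefficient of variation beyond counting noise was only 1.62% over replicates 2 and 3.

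Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, robust quasi-likelihood fit and test, group as the only term), two-sided, with Benjamini-Hochberg adjustment over the 16006 genes kept and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Normalized counts are counts divided by the effective library size and multiplied by the mean effective library size of 26348516. Means are given with the SD of the 3 libraries. Single genes were also tested with an exact permutation test of log2 CPM values.

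Gene lists were tested with camera of limma 3.58.1 on log2 CPM values with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists with at least 5 tested members. The genes named were set by a rule before the data were examined: RUVBL1, RUVBL2 and PLXNA1 among 5 fixed genes, then the 10 largest rises and 10 largest falls among named genes with an adjusted p under 0.05, no overlap between groups and a mean of at least 100 normalized counts, then the 4 members with the smallest p of each list past the threshold and of the plexin, ERK cascade and ERK output lists, among others. Some of the genes and lists that this rule names are not reported here.

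Whether the replicate numbers pair the libraries was checked by correlating deviations from the group means across tested genes. Libraries with the same number had correlations of 0.939, 0.819 and 0.823, so the numbers were taken to pair the libraries, and a fit with the replicate number as a block was an alternative. Without the genes at 0 in replicate 1 these were 0.706, 0.409 and 0.438. Replicates 2 and 3 correlated across numbers as well (0.807 and 0.817, or 0.383 and 0.411 without those genes), and the difference between replicates 2 and 3 had a correlation of only 0.035 between the groups (0.157 over genes with at least 100 normalized counts). The shared structure thus mostly sets replicate 1 apart from the others, and the values say little on whether replicates 2 and 3 are paired. The pairing comes from these values and not from a statement in the labels.

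On simulated counts with 200 changed genes, drawn for the comparison of RUVBL1 siRNA with control siRNA, 15805 genes were tested and edgeR recovered 32 of 50 genes changed 1.25-fold, 32 of 50 changed 1.5-fold, 41 of 50 changed 2-fold and 43 of 50 changed 3-fold, with 0 false calls among 148. DESeq2 and limma-voom also made 0 false calls. The fit with the block made 8 false calls among 178. The simulation changed far fewer genes than the 6755 called in the data, with random direction and with noise drawn independently for each library. It therefore did not test the centring of the fold changes or replicates that are technical, and its false calls say little on either.

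Alternatives fixed before the data were examined were the DESeq2 1.42.0 Wald test, limma-voom, DESeq2 size factors in edgeR, library size alone, no low-count filter, a filter of at least 50 counts in 3 libraries, the replicate block, each library left out in turn, an adjusted p of 0.01, a 2-fold minimum, and for lists an estimated correlation, the fry test and a prior count of 0.5. Alternatives chosen after seeing the data were replicates 2 and 3 alone, the genes at 0 in replicate 1 left out, offsets for transcript length and GC content with and without the block, library sizes without the mitochondrially encoded genes, each p bounded below by that of counting noise, the agreement of replicate 1 over genes chosen in replicates 2 and 3 alone, and the block for the gene families and the further cell cycle lists. Figures were drawn with matplotlib 3.10.9.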

Results

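RNA sequencing was used to measure gene expression in C4-2B-ENZR, a human prostate cancer cell line resistant to the prostate cancer drug enzalutamide. The cells had been transfected with a negative-control siRNA or with an siRNA against RUVBL1. RUVBL1 is an AAA+ ATPase that works with RUVBL2 in chromatin-remodelling complexes and in the assembly of large protein complexes. Each group had 3 libraries, numbered 1 to 3 in the labels. The estimated counts summed to 24720504, 36054489 and 30011235 in the control libraries and to 18985542, 25697804 and 23526449 in the RUVBL1 siRNA libraries. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

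The first question was whether the target of the siRNA, its partner RUVBL2 and PLXNA1, which the study's title names, had changed. RUVBL1 (ENSG00000175792.7) fell in all 3 RUVBL1 siRNA libraries to 57.1% ± 1.23 (SD, n = 3) of the control mean. Its normalized counts were 4681, 4654 and 4758 in the control libraries and 2725, 2618 and 2710 in the RUVBL1 siRNA libraries. The log2 fold change was -0.81 (SE 0.0253, edgeR adjusted p = 3.74e-10). PLXNA1 (ENSG00000114554.7), which encodes the semaphorin receptor plexin A1, fell to 71.6% ± 1.36 (SD, n = 3) of the control mean, from 1280 ± 60.0 to 917 ± 17.4 normalized counts (log2 fold change -0.48, edgeR adjusted p = 1.51e-06). RUVBL2 (ENSG00000183207.8) fell by 0.19 on the log2 scale (edgeR adjusted p = 0.0014), and with libraries scaled by their totals alone the change was -0.09 and missed the threshold (adjusted p = 0.0977). Each of these 3 genes separated the groups completely, and the exact two-sided permutation test gave p = 0.1 for each, the smallest p that the 20 assignments of 3 against 3 libraries allow.

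**Figure D1:**
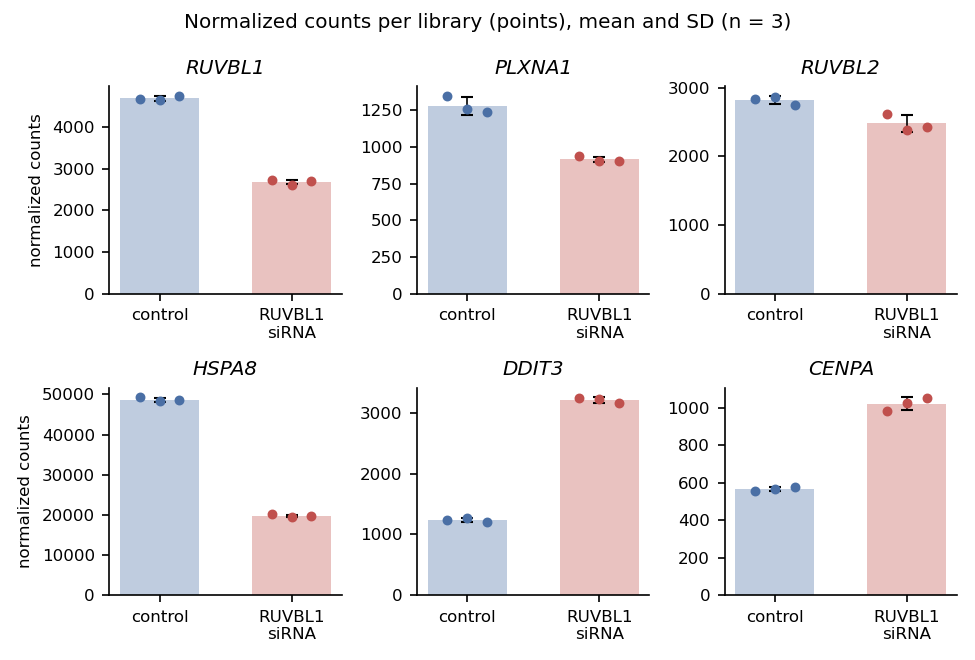
Normalized counts of 6 genes in each library (points), with the mean (bar) and SD (error bar) of the 3 control siRNA and the 3 RUVBL1 siRNA libraries; every vertical axis starts at 0. RUVBL1 lies between 4654 and 4758 in the control libraries and between 2618 and 2725 in the RUVBL1 siRNA libraries, and HSPA8 falls from a mean of 48730 to 19740.

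Across the transcriptome, many genes changed by small amounts. Of 16006 genes tested, 6755 passed an edgeR adjusted p of 0.05, with 3060 higher and 3695 lower after RUVBL1 siRNA. The median change among them was 1.22-fold. At least a 2-fold change was seen for 225 of them, 167 higher and 58 lower. With libraries scaled by their totals alone, 4981 genes were higher and 2297 lower, which is 68.4% higher against 45.3% with TMM factors, and the median log2 fold change of a gene moved by 0.0993. The groups did not overlap for 8427 genes (52.6%), where chance gives 10%. Of the 6755 genes, 6265 also passed the threshold in the same direction in replicates 2 and 3 considered without replicate 1. Those libraries also entered the 6755 calls, so this overlap is not independent. Among 7155 genes past the threshold in replicates 2 and 3 alone and above 0 in replicate 1, which had no part in their choice, 6825 (95.4%) had the same direction in replicate 1, and the fold changes had a Pearson r of 0.829 across genes, which are not independent replicates. Over all 15238 tested genes above 0 in replicate 1, 79.6% had the same direction, with an r of 0.589.

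**Figure D2:**
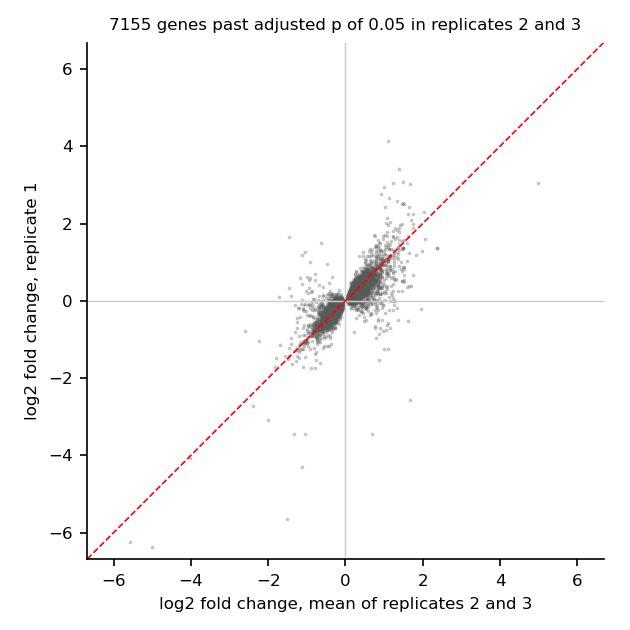
Log2 fold change (RUVBL1 siRNA against control siRNA) in replicate 1, vertical axis, against that of the mean of replicates 2 and 3, horizontal axis, for the 7155 genes (points) past an adjusted p of 0.05 in replicates 2 and 3 alone and above 0 in replicate 1; the dashed line marks equal values. The Pearson r across genes is 0.829.

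The genes with the largest rises included several of the stress response that follows activation of ATF4, a transcription factor of amino acid and endoplasmic reticulum stress. CHAC1, which encodes an enzyme that degrades glutathione, rose 3.10-fold, from 450 ± 19.3 to 1397 ± 83.3 normalized counts (SD, n = 3 each; log2 fold change 1.63, edgeR adjusted p = 4.82e-10). DDIT3, which encodes the transcription factor CHOP, rose 2.60-fold (log2 1.38, SE 0.0307), and DDIT4, which encodes an inhibitor of mTORC1 signalling, rose 2.25-fold (log2 1.17, SE 0.0212). COL16A1, a collagen chain, rose by a log2 of 1.39, TMEM160 by 1.27, the retinaldehyde dehydrogenase gene ALDH1A3 by 1.24 and the complement regulator gene CD55 by 1.23. The small nuclear RNA 7SK had a log2 fold change of 1.41, and the pseudogenes UQCRFS1P1 and ARMCX7P had 1.42 and 1.34. The values of these 3 are uncertain, since reads of near-identical copies can be shared between them and other loci. The call of ARMCX7P (edgeR adjusted p = 0.0309) was lost with the replicate block (adjusted p = 0.121), without control replicate 1 (0.0897), without RUVBL1 siRNA replicate 1 (0.0831) and without RUVBL1 siRNA replicate 2 (0.0823).

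Among the largest falls, CLU, which encodes the secreted chaperone clusterin, fell by 1.80 on the log2 scale, from 1808 ± 43.8 to 521 ± 40.9 normalized counts (SD, n = 3 each; edgeR adjusted p = 2.91e-10). HSPA8, which encodes the constitutive cytosolic HSP70 chaperone, fell by 1.30 from 48730 ± 478 to 19740 ± 325. TFRC, the transferrin receptor gene, fell by 1.26 from 13750 ± 76.4 to 5742 ± 114. ID3 and ID1, which encode inhibitors of basic helix-loop-helix transcription factors, fell by 1.24 and 1.19 on the log2 scale. TNFRSF12A, which encodes the receptor for the cytokine TWEAK, fell by 1.32, the smooth muscle actin gene ACTA2 by 1.33, the guanylate-binding protein gene GBP2 by 1.29 and GPR137C by 1.22. FAM47E-STBD1 fell by 1.45, and its estimate is uncertain because it is a readthrough gene that overlaps STBD1.

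Of 28 gene lists fixed before the data were examined, 27 had at least 5 tested members, and 11 passed an adjusted p of 0.05 in limma's camera test with a preset correlation of 0.01, with 8 lower and 3 higher. With an estimated correlation, 4 of the 11 held. These were the lists of MYC targets and ribosome biogenesis, DNA replication, heat shock chaperones and mitochondrially encoded mRNAs. Among the lists that lost their call, the estimate lay below the preset 0.01 for the RUVBL chaperone (-0.0211), plexin (-0.0379) and DNA repair (-0.00195) lists. A higher correlation of members was thus not the reason for the loss of those calls.

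**Figure D3:**
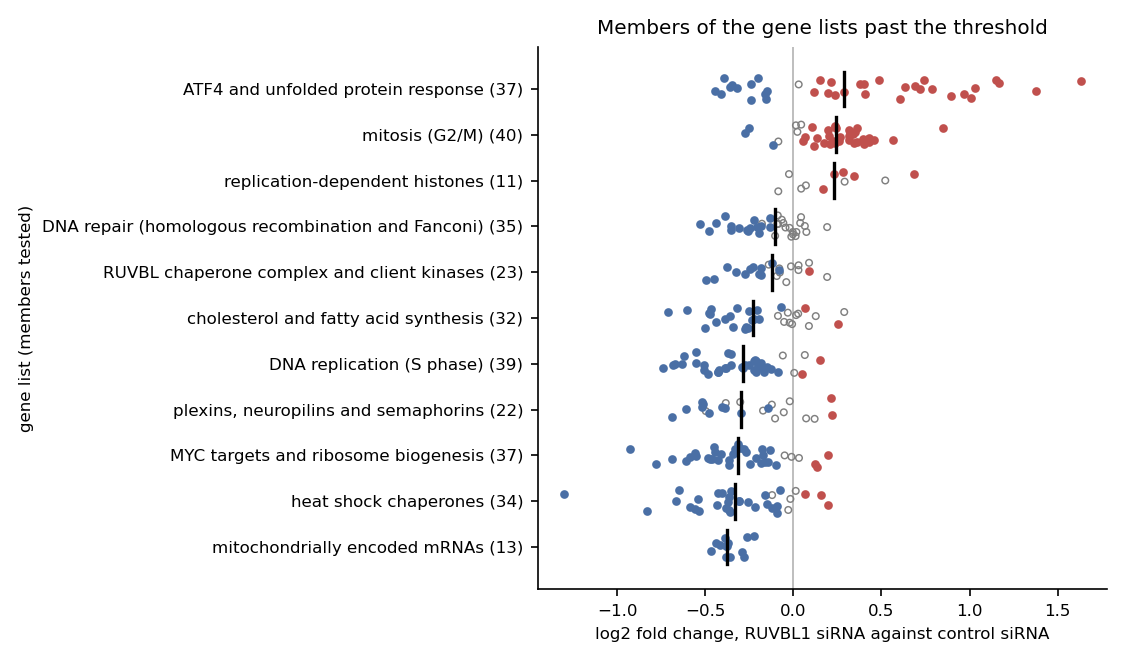
Log2 fold change (horizontal axis) of each tested member of the 11 lists past the camera threshold (rows, with the number of members tested); filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and the black bar is the list's median. The medians run from -0.38 for the mitochondrially encoded mRNAs to 0.29 for the ATF4 and unfolded protein response list.

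Most tested genes of ribosome biogenesis and DNA replication were lower. Of 37 tested MYC targets and ribosome biogenesis genes, 31 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 1.23e-09, and adjusted p = 0.0327 with an estimated correlation). RRP12, a ribosome assembly factor, fell by 0.93 on the log2 scale, MYBBP1A by 0.78, NOP56 by 0.56 and NOLC1 by 0.49. Of 39 genes of DNA replication, 34 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.48e-10, and adjusted p = 0.0327 with an estimated correlation). The licensing factor gene CDC6 fell by 0.68, the flap endonuclease gene FEN1 by 0.63, the helicase subunit gene MCM6 by 0.62 and the ribonucleotide reductase subunit gene RRM2 by 0.42. Of 35 genes of homologous recombination and the Fanconi pathway, 16 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.0925 with an estimated correlation). With libraries scaled by their totals alone, 10 of these fell and 4 rose. FANCA fell by 0.48, RAD54B by 0.44, RAD54L by 0.39 and BRCA1 by 0.26.

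Mitotic genes were mostly higher. Of 40 genes of mitosis, 33 rose and 3 fell, and adjusted over the list alone 33 rose and 4 fell (camera adjusted p = 6.97e-09, and adjusted p = 0.0943 with an estimated correlation). The centromeric histone gene CENPA rose 1.80-fold (log2 0.85), the securin gene PTTG1 1.48-fold (log2 0.56), CENPF 1.37-fold (log2 0.46) and the kinase gene NEK2 1.35-fold (log2 0.43). Of 11 histone genes on a list of replication-dependent histones, 5 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0199, and adjusted p = 0.409 with an estimated correlation). Scaling by library totals alone gave 8 that rose and 0 that fell. Among the members that rose were H2BC21 (log2 0.23), H2AC6 (0.17) and H2BC5 (0.28). The call of this list was lost without RUVBL1 siRNA replicate 2 (adjusted p = 0.0634) and in replicates 2 and 3 alone (adjusted p = 0.0653).

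Most heat shock chaperone genes were lower, while most genes of the ATF4 response were higher. Of 34 heat shock chaperone genes, 27 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 8.97e-09, and adjusted p = 0.0386 with an estimated correlation). Besides HSPA8, HSPH1 fell by 0.83 on the log2 scale and HSP90AA1, the inducible HSP90 gene, by 0.54 from 84630 ± 229 to 58330 ± 378 normalized counts (SD, n = 3 each). HSPA1B fell by 0.66, an uncertain value because its sequence is nearly identical to that of HSPA1A. Of 37 genes of ATF4 and the unfolded protein response, 24 rose and 12 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000666, and adjusted p = 0.199 with an estimated correlation). The members that rose included the asparagine synthetase gene ASNS (log2 1.15), NUPR1 (0.90), DDIT3 and DDIT4. Chosen after their values were seen, ATF4 itself rose by a log2 of 0.49, while the endoplasmic reticulum chaperone genes PDIA4, HYOU1, HSPA5 and CALR fell by 0.44, 0.41, 0.24 and 0.15.

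All 13 mitochondrially encoded mRNAs fell, also when adjusted over the list alone and with every scaling tried (camera adjusted p = 4.28e-08, and adjusted p = 0.0327 with an estimated correlation). MT-ND5 fell by 0.42 on the log2 scale, MT-CO1 by 0.38, MT-CYB by 0.37 and MT-ND4 by 0.36. Together the mitochondrial genes took 13.8%, 13.5% and 13.5% of the counts in the control libraries and 11.6%, 11.3% and 11.3% in the RUVBL1 siRNA libraries. Of 44 nuclear genes of oxidative phosphorylation, 9 rose and 12 fell, and the list was not called (camera adjusted p = 0.557). With libraries scaled by their totals alone, 28 of them rose and 5 fell. Of 32 genes of cholesterol and fatty acid synthesis, 20 fell and 2 rose, and adjusted over the list alone 20 fell and 3 rose (camera adjusted p = 3.52e-05, and adjusted p = 0.224 with an estimated correlation). With libraries scaled by their totals alone, 19 of them fell and 8 rose. The sterol demethylase gene CYP51A1 fell by 0.61 on the log2 scale and the desaturase gene FADS1 by 0.47.

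Genes tied to RUVBL1, plexins and the ERK MAPK cascade were examined next. Of 23 genes of the RUVBL chaperone complex and its client kinases, 12 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00958, and adjusted p = 0.109 with an estimated correlation), whereas 6 fell and 6 rose with libraries scaled by their totals alone, and 12 fell and 2 rose with the replicate block. MTOR fell by 0.50 on the log2 scale, PRKDC by 0.45, TRRAP by 0.38 and ECD by 0.33. Of 22 plexin, neuropilin and semaphorin genes, 10 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.0925 with an estimated correlation). Besides PLXNA1, SEMA3C and PLXNB1 each fell by 0.52 and the co-receptor gene NRP1 by 0.41. Of 32 components of the ERK MAPK cascade, 10 rose and 8 fell, and adjusted over the list alone 10 rose and 9 fell. The list was not called (camera adjusted p = 0.466), its median log2 fold change was 0.07 and its mean -0.01, and with libraries scaled by their totals alone 19 rose and 4 fell. The receptor genes FGFR1, EGFR and ERBB2 fell by 0.67, 0.46 and 0.39, and PEBP1 rose by 0.23. Of 18 genes known to respond to ERK, 2 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.792), and with libraries scaled by their totals alone 6 rose and 2 fell. EPHA2 fell by 0.41, CCND1 by 0.20 and SPRED2 rose by 0.47. JUNB fell by 0.15 and was not called with libraries scaled by their totals alone (adjusted p = 0.394).

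None of the other lists reported here was called by camera, which asks for a shared direction. The lists of epithelial-mesenchymal genes, apoptosis regulators and ERK cascade components each hold genes of opposing roles. For these lists, the test and the counts cannot decide on a change in which such genes move apart. The counts of genes that rose and fell were 10 and 6 of 31 for the INO80, SRCAP and TIP60 chromatin complexes (16 and 0 with libraries scaled by their totals alone), 4 and 2 of 9 for neuroendocrine markers and 9 and 2 of 15 for glucocorticoid receptor and bypass genes. Adjusted over the list alone they were 10 and 6, 5 and 2, and 9 and 3. They were 6 and 16 of 32 for hypoxia and glycolysis, 4 and 9 of 20 for epithelial-mesenchymal genes, 5 and 10 of 18 for luminal prostate markers and 2 and 3 of 31 for interferon-stimulated genes, and adjusted over the list alone 6 and 16, 5 and 10, 5 and 10, and 1 and 3. With libraries scaled by their totals alone, 12 rose and 11 fell on the hypoxia list, 6 and 2 on that of interferon-stimulated genes, 6 and 1 on that of neuroendocrine markers, 9 and 1 on that of glucocorticoid receptor and bypass genes and 12 and 3 on that of apoptosis regulators. With the replicate block, 4 interferon-stimulated genes rose and 5 fell, and 39 ribosomal protein genes rose and 22 fell. For NF-kappaB and inflammatory genes 2 of 12 rose and 0 fell (1 and 0 adjusted over the list alone), for apoptosis regulators 11 of 26 rose and 5 fell (also 11 and 5), and for ribosomal proteins 22 of 78 rose and 17 fell (24 and 21), or 54 and 2 with libraries scaled by their totals alone. The nuclear genes of oxidative phosphorylation gave 9 and 12 adjusted over the list alone as well. Of 7 tested stromal, endothelial and immune markers, 0 rose and 2 fell, also adjusted over the list alone, and these were ACTA2 and CD68. The list of basal epithelial markers had 3 tested members, of which 2 fell, and was not tested as a list.

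The 2 replicate 1 libraries differed from the other 4 in which genes were counted. Of 14111 genes with at least 20 counts in every library of replicates 2 and 3, 541 were listed at 0 in both replicate 1 libraries, and 375 of the 541 were long intergenic RNA genes. Of the genes chosen after their values were seen, MALAT1, a nuclear RNA, had 220263 and 183087 counts in control replicates 2 and 3 and 0 in replicate 1. None of the 541 genes passed the threshold, and 0 had an unadjusted p under 0.05 with edgeR, DESeq2 or limma-voom. With the replicate number as a block, 146 of them passed, and in replicates 2 and 3 alone 168 rose and 14 fell. These counts did not move when each p was bounded by that of counting noise. MALAT1 passed in both fits with a log2 fold change of only 0.03, and its fitted SE lay below counting noise with the block. NEAT1, the RNA of nuclear paraspeckles and also chosen after its values were seen, had 45324 and 37691 counts in the control libraries and 67469 and 61864 in the RUVBL1 siRNA libraries of those replicates, a log2 fold change of 0.96 that also passed in both fits, although its fitted SE lay below counting noise in each.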

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

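Tests on replicates 2 and 3 alone, on length and GC content, without genes at 0 in replicate 1, without mitochondrial genes and with p bounded by counting noise were chosen after seeing the data. The count of 6755 changed genes lay between 5058 and 7849 under all alternatives except the 2-fold minimum, which left 225; it was 7837 with the replicate block and between 5741 and 6357 with one library left out. At least 2-fold changes numbered 77 with at least 50 counts in 3 libraries, where fewer genes of low count were tested. They numbered 143 with DESeq2, where 1557 genes had no adjusted p, and 362 in replicates 2 and 3 alone. For neither of these was the cause tested. The fitted SE of 185 of the 6755 genes lay below counting noise, and 6751 genes passed with each p bounded by that of counting noise. With library size alone, 4981 genes were higher and 2297 lower, since the factors that set the centre of the fold changes were left out; RUVBL2 then had -0.08595 (adjusted p = 0.0977). RUVBL1, PLXNA1 and RUVBL2 missed the 2-fold minimum (log2 fold changes of -0.8075, -0.481 and -0.1853); under every other alternative run, RUVBL1 and PLXNA1 stayed lower and past the threshold.

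The 11 lists became 4 with an estimated correlation and 21 with fry, which does not compare a list with other genes; the replicate block left 11, and one library left out gave 10 to 11. With the block, ARMCX7P lost its call and 146 of the 541 genes at 0 in replicate 1, NEAT1 and MALAT1 (log2 0.03) among them, gained one; it changed the call of no other gene named here, of none of the fixed lists reported here and of none of the gene families and further cell cycle lists. None of the genes of the naming rule and fixed lists reported here that passed the threshold changed direction. Alternatives written for normalized units were not run, since the values are counts. Depth limits genes of low count: the rule for named genes asks for 100 normalized counts.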

Other observations

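The tests of 7 gene families, of depth for the genes at 0 in replicate 1, and of scaling, length and GC content for the S phase and mitotic genes were chosen only after the result was seen. Among those 7 gene families, chosen by symbol, 5 of 7 tested laminin genes fell and 0 rose (median log2 fold change -0.50, camera adjusted p = 0.000575, and adjusted p = 0.097 with an estimated correlation). LAMA5, LAMA3 and LAMC1 fell by 1.06, 0.71 and 0.69 on the log2 scale. Of 12 integrin genes, which encode receptors for such matrix proteins, 7 fell and 0 rose (camera adjusted p = 0.00997, and adjusted p = 0.097 with an estimated correlation), with ITGA3, ITGB4 and ITGB1 lower by log2 fold changes of -0.92, -0.72 and -0.44. Of 14 genes of the TNF receptor superfamily, 8 fell and 1 rose (camera adjusted p = 0.00726, and adjusted p = 0.097 with an estimated correlation), among them TNFRSF10D (-1.12), TNFRSF10A (-0.78) and FAS (-0.64). The other 4 families were not called. These were cytosolic and mitochondrial aminoacyl-tRNA synthetases (8 and 2 rose, 8 and 7 fell), collagens (4 rose, 7 fell) and small nucleolar RNA host genes. Of 24 tested host genes, 2 rose and 5 fell. Another 7 of the 24 were among the genes at 0 in replicate 1, of which 0 were called. When libraries were scaled by their totals alone, the balance turned for the mitochondrial synthetases (5 rose, 3 fell) and the host genes (5 rose, 1 fell), 10 cytosolic synthetase genes rose and 3 fell, and 4 collagen genes rose and 6 fell. That scaling gave 5 laminin genes that fell and 0 that rose, 6 and 1 integrin genes, and 6 and 2 TNF receptor genes. With the replicate block, 8 host genes rose and 9 fell. Since the families were chosen after the values were seen, their p-values are not independent evidence.

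The 541 genes at 0 in both replicate 1 libraries may have been missing from the reference used to quantify those libraries. Of 404 further long intergenic RNA genes with a mean of 5 to 19 counts in replicates 2 and 3, 92.8% were at 0 in both replicate 1 libraries, against 1.97% of 557 antisense genes with such counts, a test fixed before its result was seen. A lower depth is argued against, since the replicate 1 libraries would hold 548400 counts of the 541 genes at their depth and held 0. A library preparation that lost only part of these RNAs is argued against as well, since it would leave some counts. Of 409 long intergenic RNA genes with at least 20 counts in every library of replicates 2 and 3, 375 were under 1% of that level in replicate 1. A further 3 were at 1 to 50% and 31 at 50% or more. A preparation that lost these RNAs completely was not tested, and no biological explanation was tested.

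S phase genes were lower and mitotic genes higher, with a gap of 0.53 between the medians (log2). One scaling factor per library moves both lists alike and leaves this gap at 0.53, and with length and GC offsets it was 0.49 (0.49 with the block as well). A hypothesis is a shift of cells from S phase to G2 and mitosis. On further genes of neither list, fixed before their test, 19 of 26 S phase genes fell and 18 of 30 G2/M genes rose, a gap of 0.33 (camera adjusted p = 8.23e-05 for each; with an estimated correlation, adjusted p = 0.118 and 0.097, past the threshold for neither), against 11 and 25 with libraries scaled by their totals alone. The list of replication-dependent histones, whose mRNAs are most abundant in S phase, goes against fewer cells in S phase, with 5 of 11 higher and 0 lower (camera adjusted p = 0.0199, and adjusted p = 0.409 with an estimated correlation), so the hypothesis stays open, as do changes of transcription with no change of phase.

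Of 945 antisense RNA genes tested, 196 rose and 21 fell, with a median log2 fold change of 0.28, and 0.39 with libraries scaled by their totals alone. Low abundance is argued against as the whole cause, since protein-coding genes drawn at the same mean counts had a median of 0.0587 over 10000 draws and at most 0.12. The genes at 0 in replicate 1 do not account for it, since only 5 of the 945 antisense genes were among them. The 918 antisense genes counted in all 6 libraries had a median of 0.28, but leaving out so few genes could hardly have moved the median. Over 345 pairs the antisense gene exceeded its sense gene by a median of 0.25 (bootstrap 95% interval 0.20 to 0.29). Reads that share the sense gene's own fold change are thus argued against as the whole cause. Intronic reads of the sense gene need not share that fold change, so this comparison cannot decide on them. Among other classes, 8 of 73 sense intronic genes rose and 0 fell (median 0.26, and 14 and 0 with the replicate block). Of 6 small nuclear RNA genes, 6 rose (median 1.68), but their counts were low (median of the mean normalized counts 15.1) and only 5 were counted in all 6 libraries. Of 583 long intergenic RNA genes, 15 rose and 2 fell (median 0.27, but 0.10 over the 52 counted in all 6 libraries). However, 375 of the 583 were at 0 in both replicate 1 libraries, and 0 such genes had an unadjusted p under 0.05 in that edgeR fit. The 15 and 2 therefore come from the remaining genes alone. With the replicate block 121 of the long intergenic RNA genes rose and 9 fell. Processed pseudogenes, also of low count (median 34.7), went the other way, with 16 of 578 higher and 31 lower (median -0.03). With libraries scaled by their totals alone, 37 of the pseudogenes rose and 17 fell. A rise of intronic or nuclear RNA may remain, and without a stated strand setting single antisense genes are uncertain.

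Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. For the count of changed genes, 1 of the 10 splits, the real one, gave 6755, and the highest of the others gave 0 with edgeR (at most 244 at an unadjusted p under 0.05). Each other split put libraries of both groups in each arm, so a real group difference adds to the spread within its arms. The count of 0 is therefore no measure of what chance gives. For the gene lists, 1 of the 10 gave 11, and the highest of the others gave 7. Camera with the preset correlation called lists in splits where 0 genes passed. The arms of those splits hold unequal numbers of libraries of each group, so part of a real group difference remains between them. Their list counts are therefore no measure of what chance gives either.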
